A study of Mus musculus with 33 samples.

How the data were processed

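The non-normalized table of the authors holds, for each of 33 arrays, a probe intensity that is not on a log scale, and the values are read as intensities from their range. Beside each intensity the same deposited table holds a detection p-value per probe, in 936 steps. The series matrix holds values read as log2 intensities, quantile normalized by the authors, since all its arrays share the same set of values. The sources used here name neither the scanner software nor the authors' normalization program. Per the labels, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I, examined on a Bioanalyzer and turned into biotin-labelled cRNA with a MessageAmp kit.

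Arrays were matched between the tables by rank correlation, which was 1 for each match. The replicate numbers differed between the tables for 16 of 33 arrays, always within the same group, and the numbers used here are those of the table of intensities. The non-normalized table has 45281 probes and the series matrix 16712. The probe-to-gene table used here covers 15259 probes, of which 15254 carry 1 symbol and 5 several. Of the series matrix probes, 1453 have no name here. Entrez identifiers of 15248 probes matched the reference table, and 0 symbols changed. Probes whose signal was at detection p under 0.01 on at least 4 arrays, the size of the smallest group, were kept (21107), and 15195 of them had 1 symbol. Where a gene had several such probes (3490 genes), the probe with the highest mean stood for it, which left 10412 genes. The 5912 detected probes without a usable name were fitted apart, and 1148 of them changed at day 12 against non-pregnant uterus. Other probes of the same genes had the opposite sign at adjusted p under 0.05 in at most 13 of 1254 cases (day 12 against non-pregnant).

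Intensities were background corrected with the negative control distribution inferred from the detection p-values (limma's nec, offset 16), quantile normalized and put on log2. A linear model with 1 mean per group was fitted to all 33 arrays with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, and version 1.17.8 of data.table), with moderated t tests and Benjamini-Hochberg adjustment over the 10412 genes of a comparison. Residual degrees of freedom were 26 and prior degrees of freedom 4.43. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3. The floor of an array, its lowest normalized signal among detected probes, ran from 4.97 to 6.03 log2. For a gene that no array of a group detected, each array of that group was raised to its floor if below it, and the bound is the ratio of the other group's mean to the mean of these values, and no fold is given where both groups were undetected.

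Before the data were examined, 35 gene lists with 662 members were fixed from textbook knowledge, of which 448 members were measured and 34 lists had the 3 measured genes needed for a list test. Lists were tested with limma's camera at the preset correlation of 0.01 and, as an alternative, with a correlation estimated from the data, and by fry. Genes are named by a rule fixed at the same time: the 5 largest rises and falls that passed both thresholds without overlap between arrays for each day against non-pregnant uterus, the 3 largest between successive days, up to 4 members of each described list, and a fixed set of landmark genes. Symbols of clone type were passed over. The lists of squamous, Y-linked and imprinted genes in the closing section were fixed later, as stated there.

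The procedure was tested on simulated data with the spread of each gene around its group means. For day 12 against non-pregnant, 87 of 100 genes set 2-fold apart passed the adjusted p, 55 were called changed, all 100 of 100 set 4-fold apart passed, and of the unchanged genes 7 passed and 0 were called. For day 11 against day 10 the values were 66, 39 and 96 of 100, with 10 unchanged genes passing and 3 called. The shifted list was called in both and 0 unshifted lists were. Genes were drawn independently of each other, so the simulation says nothing of list calls where members move together.

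Alternatives fixed before the data were examined were no background correction, median scaling, cyclic loess, the series matrix values, other filters on dim probes, another probe rule, only the 2 groups compared, array weights, another variance prior, replicate blocks, other fold minima, each array left out in turn, and the list tests named above. Leaving out both dim arrays and averaging near-identical arrays were added after the data were seen. A slide block was not run, because no source used here gives the slide. Probes without a usable name were not analysed here as genes.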

Results

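The data were 33 single-colour Illumina bead arrays of total RNA from uterine tissue of 8-week-old C57BL/6 mice, an inbred laboratory strain. The groups were non-pregnant uterus (6 arrays) and tissue of the uterine microenvironment at day 4 (4 arrays), day 6 (6), day 8 (4), day 10 (4), day 11 (4) and day 12 (5) after fertilization. Depth on an array is the number of probes above background, at detection p under 0.01. It ran from 15040 probes (day 8 replicate 2) to 18692 (day 12 replicate 2) on 31 arrays, and was 13097 on non-pregnant replicate 4 and 13149 on day 6 replicate 4. The labels do not say that the arrays hold separate animals, so each p-value measures spread between samples, which may be technical. The number of arrays limits precision. Spread is pooled per gene over 7 groups, so standard errors (SE) can be too small for noisy groups (Prap1 at day 4: SD 3.90, SE 0.83). Day 4 replicates 2 and 3 differed by a median absolute difference of 0.137 log2 over 4262 bright probes and non-pregnant replicates 2 and 3 by 0.147, against 0.161 for the next closest pair of a group, and all were kept as separate samples.

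Values below are log2 differences of normalized intensity with their standard error (SE). A gene "changed" when limma's adjusted p was under 0.05 and the difference at least 2-fold, and a member of a gene list "rose" or "fell" when its adjusted p was under 0.05. Measured members given neither as risen nor as fallen did not pass. Where no array of a group detected a gene, the difference is given as "at least N-fold". Families of similar sequence, such as the prolactin-like hormones, pregnancy-specific glycoproteins, placental cathepsins, granzymes and globins, can share probe signal, so a value of a single member is uncertain in its identity.

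Across the 7 groups, 8346 of 10412 genes (80.2%) differed by limma's F test at adjusted p under 0.05, 5199 of them with at least a 2-fold range of group means. The first principal component held 47.8% of the variance and the second 19.2%. Every non-pregnant, day 4 and day 6 array lay below 0 on the first component and every day 10, 11 and 12 array above 0, with the day 8 arrays between them, while non-pregnant and day 4 arrays overlapped on both.

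**Figure D1:**
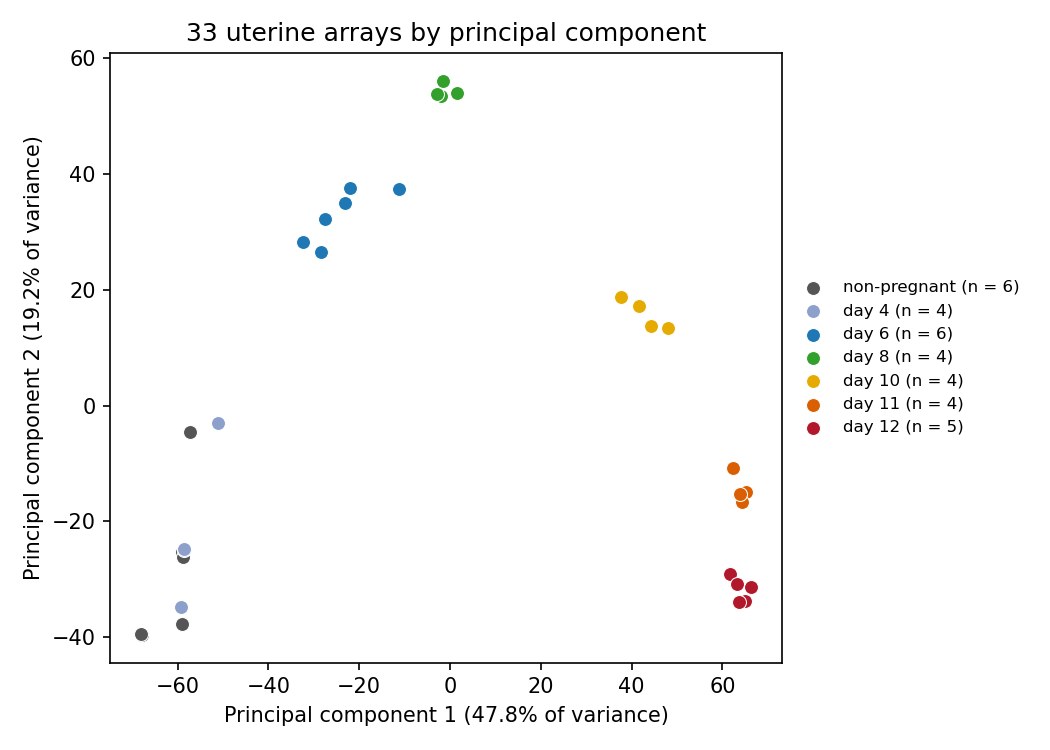
The first 2 principal components of normalized log2 intensity, in the component's own units, with 1 point per array and colours for the 7 groups. The first component (47.8% of the variance) is lowest for non-pregnant and day 4 arrays and highest for days 11 and 12, which overlap on it, and the second (19.2%) is highest at day 8.

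**Figure D2:**
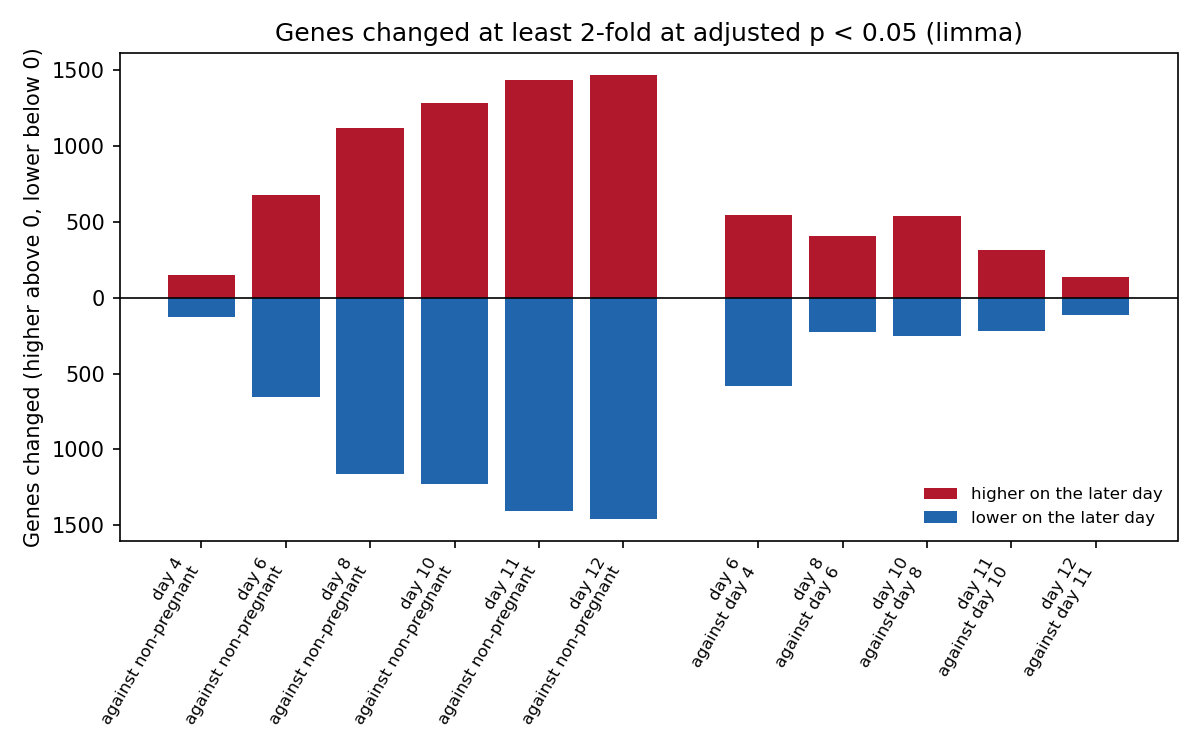
Number of genes changed at least 2-fold at adjusted p under 0.05 (limma) in each comparison, with bars above 0 for genes higher and below 0 for genes lower on the later day. Against non-pregnant uterus the number was 276 at day 4 and 2927 at day 12.

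The comparison of day 4 (4 arrays) with non-pregnant uterus (6 arrays) addressed what differs at about the time the blastocyst attaches. Pgr, the progesterone receptor, was higher by 1.44 (SE 0.20, adjusted p = 5.13e-05), and Ngfr, a neurotrophin receptor, by 1.92 (SE 0.23, adjusted p = 1.12e-05). Ccl7, a monocyte-attracting chemokine, was higher by 2.26 (SE 0.39, adjusted p = 0.000453) and Fkbp14, a prolyl isomerase of collagen folding, by 2.08 (SE 0.33, adjusted p = 0.000156). Both were detected on 4 of 6 non-pregnant arrays. Among genes without overlap between the arrays of the 2 groups, the largest falls were Prap1, a secreted protein of uterine epithelium, at -3.39 (SE 0.83, detected on 3 of 4 day 4 arrays, adjusted p = 0.0097, and -1.45 without day 4 replicate 1), C2cd4a at -2.07, and Inmt, an N-methyltransferase of indole amines, at -2.03 (SE 0.32, adjusted p = 0.000156). No array of either group detected Prl8a2, Prl3c1 or Bmp2. In all, 276 genes changed, 148 up and 128 down.

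Among the gene lists at day 4, 9 of 23 collagen and extracellular matrix genes rose, none fell and 14 did not pass (13 rose and 2 fell adjusted over the list alone), with a median of 0.71. Eln, elastin, was higher by 1.74 (SE 0.35) and Col5a1, a fibrillar collagen chain, by 1.41 (SE 0.23). The list shifted by limma's camera test (adjusted p = 0.000145), and the call was lost at adjusted p = 0.834 with an estimated correlation. Of 22 cell cycle genes, 3 rose and 19 did not pass (11 rose and 1 fell adjusted over the list alone, median 0.56, camera adjusted p = 0.000306, adjusted p = 0.893 with an estimated correlation), led by Kif11, a mitotic motor, at 0.80. Of 13 MHC class II and dendritic genes, only H2-DMb1, a peptide-loading chaperone subunit, fell, by -0.79 (1 adjusted over the list alone, median -0.43, camera adjusted p = 0.041, adjusted p = 0.893 with an estimated correlation). Of 6 adipose tissue genes, markers of another tissue, 4 fell and 2 did not pass (5 adjusted over the list alone), including the adipokine Adipoq at -2.68 and the carbonic anhydrase Car3 at -2.60. That list had a median of -1.32 and a camera adjusted p of 0.000917, lost at adjusted p = 0.834 with an estimated correlation. The day 4 count was unstable: it was 8 with only the 2 groups fitted, 101 without background correction, 106 with the series matrix values, 173 with near-identical arrays averaged, 428 without non-pregnant replicate 4, 451 without both dim arrays and 649 with array weights, and other regroupings of the same arrays gave up to 604. The share of rises was 53.6%, and 80% under median scaling, which moved the median of all genes by 0.139, so a change at day 4 is relative to that shift.

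The comparison of day 6 (6 arrays) with non-pregnant uterus (6 arrays) addressed the tissue in which decidua has begun to form. Sct, the hormone secretin, was higher by 8.48 (SE 0.31, adjusted p = 6.35e-20), with detection on 1 of 6 non-pregnant arrays. Prl8a2, the decidual prolactin-related protein, was at least 71.6-fold higher (adjusted p = 1.55e-22) and Drd4, a dopamine receptor, at least 55.01-fold (adjusted p = 1.33e-21). Tac2, the neurokinin B precursor, was higher by 6.59 (SE 0.29) with detection on 1 of 6 non-pregnant arrays, and Prss29, a gland protease of the implantation period, by 7.93 (SE 0.77) with detection on 2. The desmosomal cadherin Dsg2 was at -2.92 (SE 0.35, detected on 5 of 6 day 6 arrays, adjusted p = 8.85e-08), the epithelial adhesion gene Fermt1 at -2.85 (SE 0.29, detected on 5 of 6 day 6 arrays, adjusted p = 3.75e-09) and Plekhs1 at -3.86 (SE 0.43, detected on 5 of 6 day 6 arrays, adjusted p = 1.99e-08). In all, 1337 genes changed, 680 up and 657 down.

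At day 6, 19 of 22 decidual stroma genes rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. The median was 1.90, or 1.57 with undetected genes at their bound, and the list stood apart by camera (adjusted p = 3.26e-12, and adjusted p = 4.7e-05 with an estimated correlation). Wnt6, a secreted Wnt ligand, rose by 5.52 (SE 0.22, detected on 3 of 6 non-pregnant arrays) and Fst, an activin-binding protein, by 4.64 (SE 0.49). Of 22 cell cycle genes, 20 rose and 2 did not pass, also over the list alone (median 2.13, camera adjusted p = 4.22e-20, adjusted p = 0.0373 with an estimated correlation), among them Cdc20, an activator of the anaphase-promoting complex, at 3.30 (SE 0.21) and the mitotic kinase Aurka at 3.24 (SE 0.22). All 13 epithelial genes fell, also over the list alone, including the keratins Krt8 at -2.76 (SE 0.34) and Krt7 at -2.41 (SE 0.55, detected on 5 of 6 day 6 arrays), with a median of -2.06 (camera adjusted p = 5.88e-08, adjusted p = 0.276 with an estimated correlation). Of 13 oestrogen targets of uterine epithelium, 11 fell and 2 did not pass, also over the list alone, including Lcn2, a siderophore-binding protein, at -5.40 (SE 1.26, detected on 5 of 6 day 6 arrays), with a median of -3.38 (camera adjusted p = 3.82e-05, adjusted p = 0.537 with an estimated correlation). Non-pregnant replicate 6 stood apart on that list, with a mean of -1.12 against 2.23 to 3.60 on the other non-pregnant arrays, as did day 6 replicate 5, at 1.29 against -1.70 to -1.20.

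Macrophage, MHC class II and interferon lists were lower at day 6. Of 17 macrophage and monocyte genes, 11 fell, 1 rose and 5 did not pass (14 fell and 1 rose adjusted over the list alone, median -1.15, camera adjusted p = 0.00183, adjusted p = 0.637 with an estimated correlation). Cd14, the endotoxin co-receptor, was at -2.43 (SE 0.38, detected on 5 of 6 day 6 arrays). Of 13 MHC class II and dendritic genes, 11 fell, 1 rose and 1 did not pass, also over the list alone (median -0.94, camera adjusted p = 0.00116, adjusted p = 0.623 with an estimated correlation). H2-Aa, a class II chain, was at -1.83 (SE 0.41, detected on 5 of 6 day 6 arrays) and H2-Ab1 at -1.59 (SE 0.38). The dim arrays moved with these lists: day 6 replicate 4 had a macrophage list mean of -1.82 against -0.23 to 0.66 on the other day 6 arrays, and non-pregnant replicate 4 had -0.19 against 0.99 to 1.61. Of 17 interferon response genes, 13 fell and 4 did not pass (15 fell adjusted over the list alone, median -1.19, camera adjusted p = 3.43e-06, adjusted p = 0.512 with an estimated correlation). The RNA sensor Oas2 was at -2.19 (SE 0.34) and Oasl2 at -2.04 (SE 0.29). Of 19 endothelial and angiogenic genes, 11 rose, 2 fell and 6 did not pass, also over the list alone, including Angpt2, a Tie2 ligand, at 2.66 (SE 0.19), with a median of 0.51, or 0.50 with bounds (camera adjusted p = 0.0122, adjusted p = 0.637 with an estimated correlation). Cdh5 was at 1.79 (SE 0.25). Foxp3, the regulatory T cell factor, differed by 0.05 (SE 0.13, adjusted p = 0.802). The day 6 count was 539 without background correction and 575 with the series matrix values.

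Day 8 (4 arrays) against non-pregnant uterus (6 arrays) addressed the more advanced decidua. Prl8a2 was at least 405-fold higher (adjusted p = 5.8e-25) and Slc6a12, a betaine and GABA transporter, at least 256-fold (adjusted p = 1.32e-24). Rrm2, a subunit of ribonucleotide reductase, was higher by 7.18 (SE 0.20, adjusted p = 2.34e-23) with detection on 3 of 6 non-pregnant arrays, and Tac2 by 7.23 (SE 0.33) with detection on 1. The cornified envelope gene Sprr2f was at least 78.9-fold lower (adjusted p = 2.92e-05), the ion transport regulator Fxyd4 at least 58.99-fold (adjusted p = 1.82e-10) and the arginine-degrading enzyme Arg1 at least 36.7-fold (adjusted p = 0.00015). In all, 2284 genes changed, 1122 up and 1162 down.

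At day 8, 18 of 22 decidual stroma genes rose, 1 fell and 3 did not pass (19 rose and 1 fell adjusted over the list alone), with a median of 2.22, or 2.01 with bounds. Camera gave adjusted p = 2.65e-10, and adjusted p = 0.00018 with an estimated correlation. Prl3c1, a prolactin-like hormone of decidua, was at least 27.3-fold higher and Bmp2, a decidual morphogen, at least 5.60-fold. In the uterine natural killer list 4 of 12 genes rose, 1 fell and 7 did not pass, also over the list alone, and the camera call (median 0.21, adjusted p = 0.0365) was lost at adjusted p = 0.59 with an estimated correlation. The granzyme Gzmd rose by 7.08 (SE 0.30), with detection on 4 of 6 non-pregnant arrays, while Prf1, perforin, differed by 0.16 (SE 0.26, adjusted p = 0.639). Of 15 unfolded protein response genes, 10 rose, 3 fell and 2 did not pass (11 rose and 3 fell adjusted over the list alone), with Sdf2l1, a chaperone cofactor, at 2.54 (SE 0.22, detected on 5 of 6 non-pregnant arrays) and Calr, calreticulin, at 2.06 (SE 0.40). The list had a median of 0.88 (camera adjusted p = 0.0195, adjusted p = 0.0821 with an estimated correlation). Of 22 cell cycle genes, 20 rose and 2 did not pass, also over the list alone (median 1.90, camera adjusted p = 1.71e-11, adjusted p = 0.185 with an estimated correlation). Cdk1 was at 2.76 (SE 0.25) and Cdc20 at 2.69 (SE 0.23). Of 19 endothelial genes, 10 rose, 2 fell and 7 did not pass (11 rose and 2 fell adjusted over the list alone, median 0.57, camera adjusted p = 0.0232, adjusted p = 0.648 with an estimated correlation). Pecam1, an endothelial adhesion molecule, was at 1.40 (SE 0.25). Angpt2 was at 4.72 (SE 0.21) and Cdh5 at 1.95 (SE 0.28).

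At day 8, 12 of 13 epithelial genes fell and 1 did not pass (13 fell adjusted over the list alone, median -2.29, camera adjusted p = 1.09e-06, adjusted p = 0.419 with an estimated correlation). Elf3, an epithelial transcription factor, was at -4.78 (SE 0.81) and detection on 2 of 4 day 8 arrays. Of 13 oestrogen targets, 11 fell and 2 did not pass, also over the list alone, with Ltf, lactoferrin, at -6.12 (SE 1.00) and a list median of -3.23, or -2.498 with bounds (camera adjusted p = 0.00169, adjusted p = 0.59 with an estimated correlation). Lcn2 was at -4.97 (SE 1.41). Ltf was 8.59 on non-pregnant replicate 6 against 14.67 to 14.92 on the other non-pregnant arrays. Macrophage genes fell in 11 of 17 cases and rose in 2, also over the list alone (median -1.03, camera adjusted p = 0.048, adjusted p = 0.68 with an estimated correlation). Adgre1, the F4/80 antigen, was at -1.99 (SE 0.37, detected on 3 of 4 day 8 arrays) and Ly6c1, which endothelium also expresses, at 3.67 (SE 0.28). Of 13 MHC class II genes, 12 fell and 1 did not pass, also over the list alone (median -1.61, camera adjusted p = 0.00122, adjusted p = 0.59 with an estimated correlation). H2-Aa was at -2.72 (SE 0.45) and H2-Ab1 at -1.97 (SE 0.43). Of 17 interferon genes, 8 fell and 9 did not pass, also over the list alone (median -0.79, camera adjusted p = 0.0195, adjusted p = 0.68 with an estimated correlation). Ifi27l2a was at -2.20 (SE 0.30) and Oasl2 at -1.84 (SE 0.32). The dim non-pregnant replicate 4 had a mean of -0.13 on the MHC class II list against 1.40 to 1.68 on the other non-pregnant arrays. All 6 adipose genes fell, also over the list alone (median -2.11, camera adjusted p = 0.048, adjusted p = 0.658 with an estimated correlation). Adipoq was at -2.93 (SE 0.83). The day 8 count was 1029 without background correction and 1088 with the series matrix values.

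Day 10 (4 arrays) against non-pregnant uterus (6 arrays) addressed the tissue when embryo and placenta are growing. The embryonic globins Hbb-y and Hbb-bh1 were at least 493-fold and 489-fold higher (adjusted p = 2.27e-34 and 1.08e-29), and the trophoblast hormone Prl4a1 at least 314-fold (adjusted p = 3.3e-27). Cyp17a1, an enzyme of androgen synthesis, was at least 66.5-fold higher (adjusted p = 5.95e-26) and Cyp11a1, the cholesterol side-chain cleavage enzyme, at least 20.5-fold (adjusted p = 7.57e-23). Fxyd4 was at least 60.7-fold lower (adjusted p = 8.76e-11), and the carboxylesterase Ces1d was at -5.44 (SE 0.43, adjusted p = 2.93e-12). In all, 2514 genes changed, 1286 up and 1228 down (51.2% up, and 61.5% with a 4-fold minimum).

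All 4 lists of conceptus tissue rose at day 10, and each camera call held with an estimated correlation. Of 27 trophoblast and placental hormone genes, 19 rose and 8 did not pass (20 rose adjusted over the list alone), with a median of 1.80, or 1.05 with bounds (camera adjusted p = 9.82e-15, adjusted p = 0.000287 with an estimated correlation). Rhox9, a placental homeobox gene, was at least 256-fold higher. Of 14 yolk sac and visceral endoderm genes, 13 rose, also over the list alone, with Apoa1, an apolipoprotein, at least 53.02-fold higher and a list median of 2.73, or 1.97 with bounds (camera adjusted p = 4.32e-13, adjusted p = 0.000862 with an estimated correlation). Of 13 erythroid genes, 12 rose (13 adjusted over the list alone, median 1.11, camera adjusted p = 4.68e-09, adjusted p = 0.000287 with an estimated correlation). Hba-x was at least 260-fold higher and Slc4a1, an anion exchanger, was at 6.64 (SE 0.17, detected on 1 of 6 non-pregnant arrays). Of 14 embryonic tissue genes, 11 rose and 1 fell, also over the list alone, with the growth factor Igf2 at 4.75 (SE 0.25) and a median of 1.80 (camera adjusted p = 1.88e-06, adjusted p = 0.00262 with an estimated correlation). Of 12 steroid and prostaglandin genes, 8 rose and 3 fell, also over the list alone (median 2.40, or 2.16 with bounds, camera adjusted p = 0.00216, adjusted p = 0.00638 with an estimated correlation). Hsd11b1 was at 3.45 (SE 0.49).

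Among other lists at day 10, 15 of 22 decidual stroma genes rose, 1 fell and 6 did not pass (16 rose and 1 fell adjusted over the list alone, median 1.72, or 1.29 with bounds, camera adjusted p = 8.26e-06, adjusted p = 0.00262 with an estimated correlation). Angpt2 was at 4.97 (SE 0.21) and Fst at 4.16 (SE 0.55). In the uterine natural killer list 8 of 12 genes rose and 1 fell, also over the list alone (median 1.59, or 1.25 with bounds, camera adjusted p = 0.000281, adjusted p = 0.132 with an estimated correlation). Gzmd was at 8.66 (SE 0.30, detected on 4 of 6 non-pregnant arrays), Klrg1, an inhibitory receptor, at 3.93 (SE 0.34, detected on 4 of 6 non-pregnant arrays) and Prf1 at 1.76 (SE 0.26). Of 15 immune regulatory molecules, 8 rose and 2 fell, also over the list alone (median 0.79, camera adjusted p = 0.0242, adjusted p = 0.227 with an estimated correlation). Havcr2, the Tim-3 receptor, was at 4.23 (SE 0.17) with detection on 3 of 6 non-pregnant arrays, and Ido1, a tryptophan-degrading enzyme, at 2.95 (SE 0.18) with detection on 1. Of 15 unfolded protein response genes, 12 rose and 1 fell, also over the list alone (median 1.22, or 0.89 with bounds, camera adjusted p = 0.00125, adjusted p = 0.00408 with an estimated correlation). Calr was at 1.81 (SE 0.40). Of 22 cell cycle genes, 20 rose (21 adjusted over the list alone, median 2.05, camera adjusted p = 4.35e-11, adjusted p = 0.0872 with an estimated correlation). Aurka was at 2.82 (SE 0.24) and Cdc20 at 2.79 (SE 0.23).

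The lists that fell at day 10 lay beside the rise of the conceptus lists. Of 15 smooth muscle genes, 9 fell, 1 rose and 5 did not pass, also over the list alone (median -0.89, camera adjusted p = 0.00891, adjusted p = 0.621 with an estimated correlation). Non-pregnant replicate 4 was at 1.52 on this list against 0.14 to 0.54 on the other non-pregnant arrays, and the median without it was -0.67 (camera adjusted p = 0.0482). Myl9, a myosin light chain, was at -1.86 (SE 0.21) and Myh11 at -1.67 (SE 0.29). Macrophage genes fell in 15 of 17 cases and rose in 2, also over the list alone (median -1.59, camera adjusted p = 0.00328, adjusted p = 0.591 with an estimated correlation). The complement subunit gene C1qc was at -2.64 (SE 0.62) and C1qb at -2.54 (SE 0.55). Of 13 MHC class II genes, 12 fell, also over the list alone (median -2.04, or -2.00 with bounds, camera adjusted p = 4.36e-05, adjusted p = 0.263 with an estimated correlation). H2-Ab1 was at -2.84 (SE 0.43) and Cd74 at -2.82 (SE 0.64). Of 13 oestrogen targets, 11 fell and 1 rose, also over the list alone (median -2.84, or -2.33 with bounds and -2.93 without the low non-pregnant replicate 6, camera adjusted p = 0.0101, adjusted p = 0.621 with an estimated correlation). Sprr2f was at -5.51 (SE 1.27) and Ltf at -5.14 (SE 1.00). The day 10 count was 1159 without background correction and 1232 with the series matrix values.

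Day 11 (4 arrays) against non-pregnant uterus (6 arrays) put the same question a day later. Hbb-y was at least 695-fold higher (adjusted p = 5.06e-35), the embryonic alpha-like globin Hba-x at least 500-fold (adjusted p = 1.14e-32) and the placental cathepsin Ctsj at least 459-fold (adjusted p = 3.65e-29). Sct was at 9.57 (SE 0.34, detected on 1 of 6 non-pregnant arrays, adjusted p = 4.53e-21). Ces1d was at -6.64 (SE 0.43, adjusted p = 2.02e-14), with detection on 1 of 4 day 11 arrays, and Ltf at -6.55 (SE 1.00, adjusted p = 1.61e-06). In all, 2843 genes changed, 1437 up and 1406 down.

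At day 11 trophoblast genes rose in 25 of 27 cases, also over the list alone (median 2.91, or 2.08 with bounds, camera adjusted p = 2.34e-20, adjusted p = 2.76e-05 with an estimated correlation). All 14 yolk sac genes rose, also over the list alone (median 4.19, or 3.43 with bounds, camera adjusted p = 2.08e-14, adjusted p = 0.000462 with an estimated correlation). Apoa1 was at least 128-fold higher. All 13 erythroid genes rose, also over the list alone (median 2.21, camera adjusted p = 2.7e-11, adjusted p = 5.24e-05 with an estimated correlation). Slc4a1 was at 7.93 (SE 0.17, detected on 1 of 6 non-pregnant arrays). Of 14 embryonic genes, 11 rose, also over the list alone (median 2.47, camera adjusted p = 2.91e-08, adjusted p = 0.000605 with an estimated correlation). Igf2 was at 5.42 (SE 0.25). All 22 cell cycle genes rose, also over the list alone (median 2.49, camera adjusted p = 2.3e-12, adjusted p = 0.0718 with an estimated correlation). The spindle protein Birc5 was at 3.35 (SE 0.18) and Cdc20 at 3.40 (SE 0.23). Of 22 decidual genes, 12 rose and 1 fell, also over the list alone (median 1.15, or 0.59 with bounds, camera adjusted p = 0.00653, adjusted p = 0.0718 with an estimated correlation). Angpt2 was at 3.99 (SE 0.21) and Fst at 3.01 (SE 0.55). Of 12 natural killer genes, 7 rose and 3 fell, also over the list alone (median 0.99, or 0.68 with bounds, camera adjusted p = 0.0124, adjusted p = 0.331 with an estimated correlation). Gzmd was at 8.38 (SE 0.30, detected on 4 of 6 non-pregnant arrays) and Klrg1 at 3.14 (SE 0.34, detected on 4 of 6 non-pregnant arrays). Of 15 unfolded protein response genes, 11 rose and 1 fell, also over the list alone (median 0.89, or 0.88 with bounds, camera adjusted p = 0.0124, adjusted p = 0.0447 with an estimated correlation). Sdf2l1 was at 2.12 (SE 0.22, detected on 5 of 6 non-pregnant arrays) and Trib3, a stress pseudokinase, at 1.85 (SE 0.17, detected on 5 of 6 non-pregnant arrays).

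Of 15 smooth muscle genes at day 11, 13 fell, also over the list alone (median -1.44, or -1.22 without the high non-pregnant replicate 4, camera adjusted p = 2.12e-05, adjusted p = 0.331 with an estimated correlation). Myl9 was at -2.87 (SE 0.21) and Myh11 at -2.71 (SE 0.29). Of 17 macrophage genes, 15 fell and 2 rose, also over the list alone (median -2.93, or -2.56 with bounds, camera adjusted p = 6.31e-05, adjusted p = 0.331 with an estimated correlation). Lyz2, a lysozyme, was at -5.15 (SE 0.85) and C1qb at -4.22 (SE 0.55). Of 13 MHC class II genes, 11 fell, also over the list alone (median -2.13, or -1.51 with bounds, camera adjusted p = 1.03e-05, adjusted p = 0.247 with an estimated correlation). Cd74, the invariant chain, was at -4.69 (SE 0.64) and H2-Eb1 at -4.07 (SE 0.44). Interferon genes fell in 11 of 17 cases (12 fell and 1 rose adjusted over the list alone, median -1.21, camera adjusted p = 0.00271, adjusted p = 0.368 with an estimated correlation). Ifi27l2a was at -2.33 (SE 0.30) and Irf1 at -2.22 (SE 0.13). Chemokine genes fell in 12 of 17 cases and rose in 2 (13 and 2 adjusted over the list alone, median -0.75, or -0.74 with bounds, camera adjusted p = 0.0307, adjusted p = 0.381 with an estimated correlation). The eosinophil attractant Ccl11 was at -3.14 (SE 0.60) and Cxcl14 at 2.38 (SE 0.40). Of 8 complement genes, 5 fell, also over the list alone (median -1.86, or -1.55 with bounds, camera adjusted p = 0.0109, adjusted p = 0.361 with an estimated correlation). Cfp was at -1.90 (SE 0.18). Of 23 matrix genes, 13 fell and 3 rose, also over the list alone (median -0.72, camera adjusted p = 0.00889, adjusted p = 0.361 with an estimated correlation). Lum, a small proteoglycan, was at -2.98 (SE 0.57) and Timp2 at -2.56 (SE 0.18). Oestrogen targets fell in 10 of 13 cases and rose in 1 (11 and 1 adjusted over the list alone, median -2.05, or -2.56 without the low non-pregnant replicate 6, camera adjusted p = 0.00762, adjusted p = 0.382 with an estimated correlation). Ltf was at -6.55 (SE 1.00) and Lcn2 at -5.81 (SE 1.41). All 6 adipose genes fell, also over the list alone (median -2.38, or -1.95 with bounds, camera adjusted p = 0.0124, adjusted p = 0.361 with an estimated correlation). Car3 was at least 10.3-fold lower and Thrsp, a lipogenic factor, at least 4.40-fold. The day 11 count was 1282 without background correction and 1373 with the series matrix values.

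Day 12 (5 arrays) against non-pregnant uterus (6 arrays) was the latest stage. Hbb-y was at least 720-fold higher (adjusted p = 6.24e-36), Hba-x at least 648-fold (adjusted p = 5.22e-34), and the placental cathepsins Ctsj and Ctsq at least 464-fold and 185-fold (adjusted p = 2.88e-30 and 8.37e-31). Afp, alpha-fetoprotein, was at least 30.2-fold higher (adjusted p = 3.35e-23). Cbr2, a carbonyl reductase, was at -6.86 (SE 0.67, adjusted p = 2.94e-10) with detection on 4 of 5 day 12 arrays, and Ces1d was at least 85.0-fold lower (adjusted p = 1.22e-15). Esr1, the oestrogen receptor, was at -2.19 (SE 0.33, adjusted p = 1.35e-06), and Foxp3 differed by -0.07 (SE 0.14, adjusted p = 0.676). Foxp3 averaged 8.90 while the T cell gene Cd3e was undetected, so it may not track T cells. In all, 2927 genes changed, 1469 up and 1458 down.

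At day 12 all 27 trophoblast genes, 14 yolk sac genes, 13 erythroid genes and 22 cell cycle genes rose, also over each list alone. Trophoblast genes had a median of 5.15, or 4.48 with bounds (camera adjusted p = 1.84e-25, adjusted p = 4.05e-06 with an estimated correlation), and the pregnancy-specific glycoprotein Psg21 was at least 265-fold higher. The yolk sac median was 4.79, or 4.39 with bounds (camera adjusted p = 4e-14, adjusted p = 0.000527 with an estimated correlation), and the erythroid median 3.01, or 2.65 with bounds (camera adjusted p = 2.26e-12, adjusted p = 2.29e-05 with an estimated correlation). Slc4a1 was at 8.38 (SE 0.16), with detection on 1 of 6 non-pregnant arrays. The cell cycle median was 2.53 (camera adjusted p = 8.7e-12, adjusted p = 0.12 with an estimated correlation). Birc5 was at 3.46 (SE 0.17) and Cdk1 at 3.35 (SE 0.23). Of 14 embryonic genes, 11 rose, also over the list alone (median 2.55, camera adjusted p = 1.55e-07, adjusted p = 0.0011 with an estimated correlation). Dlk1, a Notch-like ligand, was at 8.41 (SE 0.18) and detection on 1 of 6 non-pregnant arrays. Igf2 was at 5.72 (SE 0.23).

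Of 15 smooth muscle genes at day 12, 13 fell (14 adjusted over the list alone, median -1.77, or -1.60 without the high non-pregnant replicate 4, camera adjusted p = 2.79e-06, adjusted p = 0.347 with an estimated correlation). Myh11, smooth muscle myosin, was at -3.28 (SE 0.27) and Myl9 at -2.87 (SE 0.19). Macrophage genes fell in 15 of 17 cases and rose in 1, also over the list alone (median -2.53, camera adjusted p = 0.000162, adjusted p = 0.347 with an estimated correlation). Lyz2 was at -4.16 (SE 0.80) and C1qc at -3.64 (SE 0.58). Of 13 MHC class II genes, 11 fell, also over the list alone (median -2.28, or -1.60 with bounds, camera adjusted p = 1.96e-05, adjusted p = 0.347 with an estimated correlation). H2-Eb1 was at -4.49 (SE 0.41) and H2-Ab1 at -4.16 (SE 0.40). Interferon genes fell in 13 of 17 cases, also over the list alone (median -1.50, or -1.24 with bounds, camera adjusted p = 0.000162, adjusted p = 0.347 with an estimated correlation). The transcription factor Irf1 was at -2.77 (SE 0.12) and Oas2 at -3.15 (SE 0.36). Chemokine genes fell in 13 of 17 cases and rose in 3, also over the list alone (median -1.14, or -1.01 with bounds, camera adjusted p = 0.0242, adjusted p = 0.377 with an estimated correlation). Ccl4 was at -1.74 (SE 0.42, detected on 5 of 6 non-pregnant arrays) and Ccl5 at -2.07 (SE 0.43, detected on 4 of 5 day 12 arrays and 5 of 6 non-pregnant arrays). Complement genes fell in 6 of 8 cases and rose in 1, also over the list alone (median -1.89, or -1.62 with bounds, camera adjusted p = 0.0243, adjusted p = 0.393 with an estimated correlation). C1qb was at -3.60 (SE 0.52). Oestrogen targets fell in 12 of 13 cases, also over the list alone (median -2.80, or -2.59 with bounds and -3.44 without the low non-pregnant replicate 6, camera adjusted p = 0.0018, adjusted p = 0.377 with an estimated correlation). Ltf was at -6.82 (SE 0.94) and Lcn2 at -4.83 (SE 1.32). All 6 adipose genes fell, also over the list alone (median -2.57, or -1.80 with bounds, camera adjusted p = 0.0162, adjusted p = 0.377 with an estimated correlation). Car3 was at least 10.9-fold lower and Thrsp at least 4.67-fold. The day 12 count was 1298 without background correction and 1403 with the series matrix values.

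**Figure D3:**
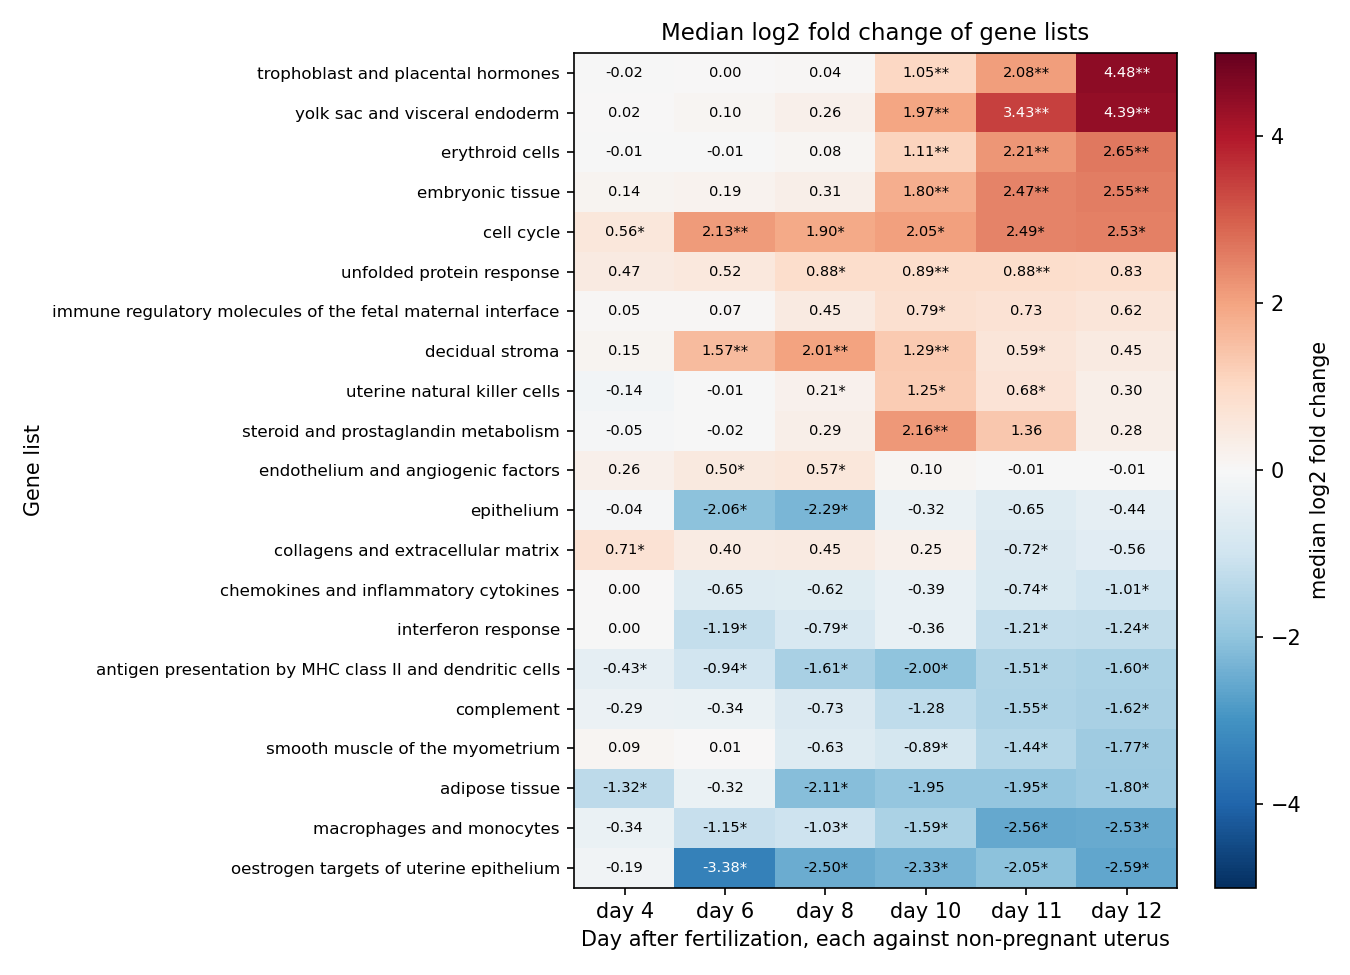
Median log2 fold change of each list shifted on at least 1 day, with undetected genes at their bound, for 6 days (columns) against non-pregnant uterus. An asterisk marks camera adjusted p under 0.05 and a double asterisk the same with an estimated correlation; the trophoblast median runs from -0.02 at day 4 to 4.48 at day 12.

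**Figure D4:**
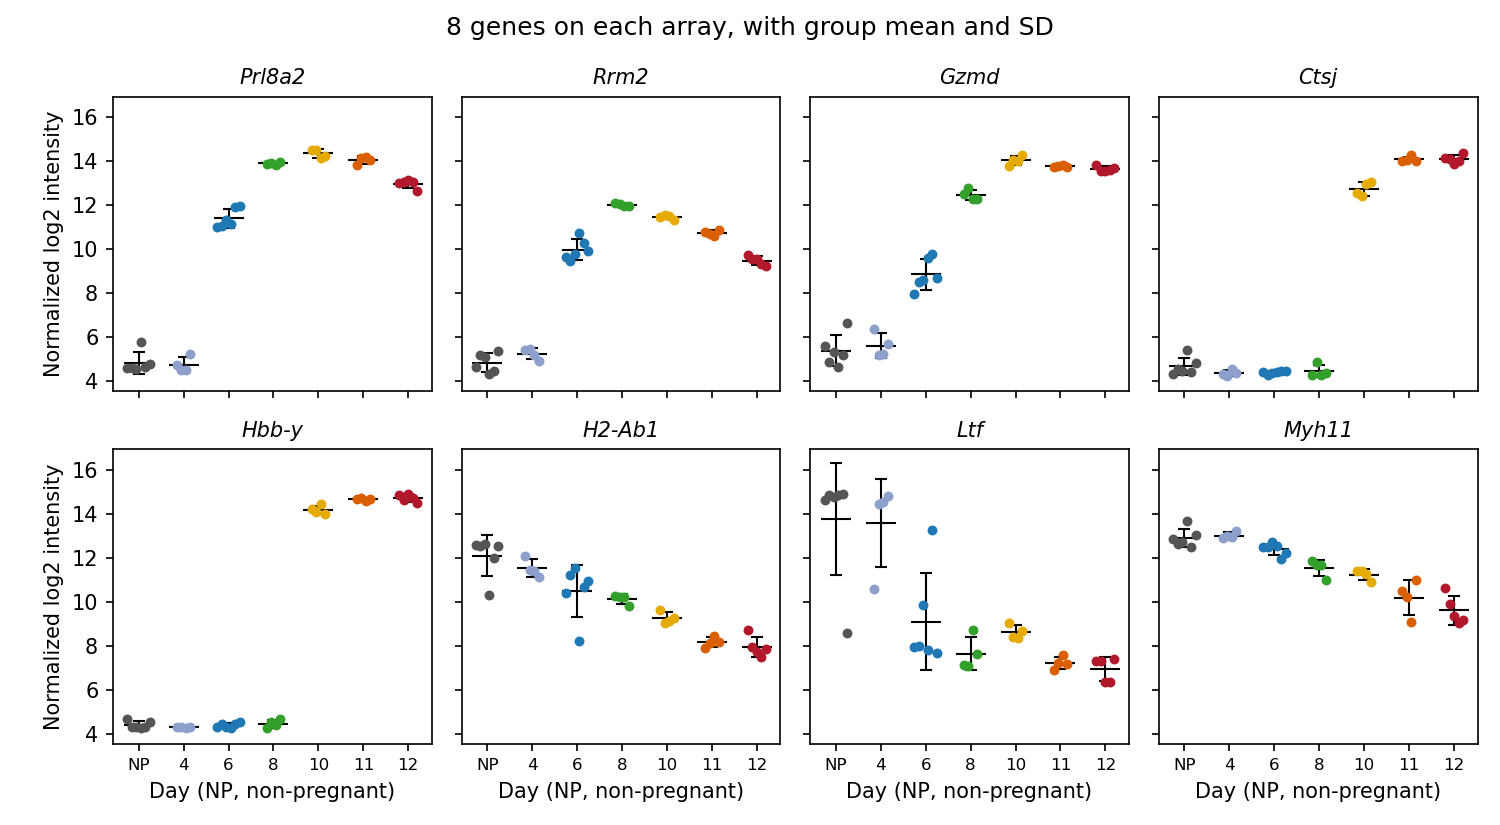
Normalized log2 intensity of 8 genes on each of the 33 arrays by day (NP, non-pregnant), as points with the group mean and SD as bars. Hbb-y is high on every array of days 10 to 12, and Ltf stands apart on non-pregnant replicate 6 at 8.59.

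Successive days were compared to ask when each shift appeared. From day 4 (4 arrays) to day 6 (6 arrays) Prl8a2 rose at least 76.6-fold (adjusted p = 3.18e-21) and Sct by 7.19 (SE 0.34, detected on 3 of 4 day 4 arrays, adjusted p = 7.13e-17). The gland proteases Prss29 and Prss28 rose by 8.04 (SE 0.86) and 7.48 (SE 0.83). Both were detected on 3 of 4 day 4 arrays. The stratified epithelial keratins Krt14 and Krt13 fell, at -6.85 (SE 1.03, adjusted p = 5.89e-06) and -3.99 (SE 0.72, adjusted p = 7.51e-05), with detection on 2 and 1 of 6 day 6 arrays. Cxcl14, a chemokine of decidua, rose by 3.62 (SE 0.40). Of 22 decidual genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone, median 1.94, or 1.61 with bounds, camera adjusted p = 2.66e-13, adjusted p = 2.32e-05 with an estimated correlation), and of 22 cell cycle genes 20 rose (21 adjusted over the list alone, median 1.62, camera adjusted p = 6.32e-19, adjusted p = 0.0481 with an estimated correlation). Oestrogen targets fell in 12 of 13 cases, also over the list alone (median -3.33, camera adjusted p = 1.38e-06, adjusted p = 0.475 with an estimated correlation). Padi1 was at -4.74 (SE 0.89). On that list day 4 replicate 1 had a mean of -1.14 against 3.00 to 3.58 on the other day 4 arrays.

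Epithelial genes fell in 10 of 13 cases between day 4 and day 6 (13 adjusted over the list alone, median -1.48, camera adjusted p = 6.42e-08, adjusted p = 0.373 with an estimated correlation). Krt8 was at -2.97 (SE 0.38). Interferon genes fell in 11 of 17 cases (12 adjusted over the list alone, median -1.08, or -1.22 without the low day 4 replicate 1, camera adjusted p = 2.56e-06, adjusted p = 0.496 with an estimated correlation) and macrophage genes in 5 of 17, also over the list alone (median -0.76, camera adjusted p = 0.0175, adjusted p = 0.718 with an estimated correlation). The dim day 6 replicate 4 was at -1.82 on the macrophage list. In all, 1129 genes changed, 545 up and 584 down (48.3% up, and 38.4% under median scaling). The count was 476 without background correction and 508 with the series matrix values, and median scaling moved the median of all genes by -0.132.

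From day 6 (6 arrays) to day 8 (4 arrays) Ntn5, a netrin family member, rose by 4.75 (SE 0.30, adjusted p = 1.31e-13), Cbln1, a synapse organizer, by 4.74 (SE 0.29, adjusted p = 4.33e-14) and Havcr2 by 4.30 (SE 0.17, adjusted p = 4.8e-18). Havcr2 was detected on 3 of 6 day 6 arrays. Aldh3a1, an aldehyde dehydrogenase, rose by 4.79 (SE 0.28) with detection on 1 of 6 day 6 arrays. The oviductal glycoprotein Ovgp1 was at -2.41 (SE 0.51, detected on 2 of 4 day 8 arrays, adjusted p = 0.000763), and Slc1a1, a glutamate transporter, at -2.50 (SE 0.33, adjusted p = 7.57e-07). In the decidual list 7 of 22 genes rose and 2 fell, also over the list alone (median 0.34, camera adjusted p = 0.00883, adjusted p = 0.122 with an estimated correlation). Prl3c1 was at 2.43 (SE 0.30). Natural killer genes rose in 4 of 12 cases, also over the list alone, with Gzmd at 3.61 (SE 0.30) and a median of 0.35 (camera adjusted p = 0.000793, adjusted p = 0.223 with an estimated correlation). Immune regulatory genes rose in 5 of 15 cases and fell in 2, also over the list alone (median 0.54, camera adjusted p = 0.0353, adjusted p = 0.329 with an estimated correlation). Lgals3 was at 1.48 (SE 0.20). Of 12 steroid and prostaglandin genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.0353, adjusted p = 0.122 with an estimated correlation). Hsd11b1, a glucocorticoid-activating enzyme, was at 3.08 (SE 0.49, detected on 5 of 6 day 6 arrays) and Ptges at 1.93 (SE 0.25).

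Also between day 6 and day 8, unfolded protein response genes rose in 3 of 15 cases and fell in 1, also over the list alone, with the co-chaperone Dnajb9 at 1.17 (SE 0.25) and a median of 0.30 (camera adjusted p = 0.0489, adjusted p = 0.122 with an estimated correlation). Sdf2l1 was at 0.93 (SE 0.22). Smooth muscle genes fell in 9 of 15 cases (10 adjusted over the list alone, median -0.61, camera adjusted p = 0.00169, adjusted p = 0.626 with an estimated correlation), and adipose genes in 4 of 6 (6 adjusted over the list alone, median -1.68, camera adjusted p = 0.00883, adjusted p = 0.557 with an estimated correlation). The dim day 6 replicate 4 stood apart on both lists, at 1.23 against 0.35 to 0.59 for smooth muscle and -0.77 against 0.99 to 2.04 for adipose tissue. In all, 636 genes changed, 407 up and 229 down (64.0% up, 77.3% under median scaling, 49.6% with no fold minimum and 87.2% with a 4-fold minimum). The count was 242 without background correction and 256 with the series matrix values.

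From day 8 (4 arrays) to day 10 (4 arrays) the embryonic globins appeared: Hbb-y rose at least 468-fold (adjusted p = 4.17e-33) and Hba-x at least 247-fold (adjusted p = 3.34e-30). Cyp17a1 rose at least 63.2-fold (adjusted p = 1.18e-23). Drd4 was at -4.21 (SE 0.24, adjusted p = 5.73e-15) and Prss28 at -4.81 (SE 0.91, adjusted p = 0.000186). Trophoblast genes rose in 19 of 27 cases (21 adjusted over the list alone, median 1.75, or 0.97 with bounds, camera adjusted p = 5.37e-33, adjusted p = 1.93e-07 with an estimated correlation). Ctsj rose at least 173-fold and Rhox9 by 7.69 (SE 0.24, detected on 2 of 4 day 8 arrays). Of 14 yolk sac genes, 13 rose, also over the list alone, with the apolipoprotein Apom at 4.71 (SE 0.21) and a median of 2.44, or 1.90 with bounds (camera adjusted p = 8.27e-28, adjusted p = 2.88e-06 with an estimated correlation). Ttr was at 5.19 (SE 0.40). Erythroid genes rose in 10 of 13 cases (12 adjusted over the list alone, median 1.78, or 1.46 with bounds, camera adjusted p = 5.99e-21, adjusted p = 1.93e-07 with an estimated correlation). Slc4a1 was at 6.19 (SE 0.18, detected on 1 of 4 day 8 arrays). Embryonic genes rose in 12 of 14 cases and fell in 1, also over the list alone (median 1.98, camera adjusted p = 5.86e-15, adjusted p = 6.03e-06 with an estimated correlation). Dlk1 was at 3.87 (SE 0.21) and Igf2 at 3.85 (SE 0.27). The epithelial list rose beside them, with 8 of 13 genes higher, also over the list alone, including Krt8 at 3.82 (SE 0.42) and Krt18 at 2.68 (SE 0.22), keratins that trophoblast also expresses (median 1.05, camera adjusted p = 5.01e-05, adjusted p = 0.302 with an estimated correlation).

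Natural killer genes rose in 7 of 12 cases between day 8 and day 10 (7 rose and 1 fell adjusted over the list alone, median 1.22, or 0.94 with bounds, camera adjusted p = 2.57e-05, adjusted p = 0.0777 with an estimated correlation), including Prf1 at 1.60 (SE 0.28) and Gzmg at 3.40 (SE 0.23). Gzme was at 2.18 (SE 0.22). Immune regulatory genes rose in 4 of 15 cases and fell in 1 (5 and 1 adjusted over the list alone, median 0.62, camera adjusted p = 0.0341, adjusted p = 0.253 with an estimated correlation). Ido1 was at 1.97 (SE 0.20) and Lgals3 at 1.33 (SE 0.22). Of 12 steroid and prostaglandin genes, 6 rose and 2 fell, also over the list alone (median 0.44, camera adjusted p = 0.0278, adjusted p = 0.0508 with an estimated correlation). Akr1c18 was at 3.10 (SE 0.54). Decidual genes fell in 7 of 22 cases and rose in 2 (8 and 2 adjusted over the list alone, median -0.52, camera adjusted p = 0.00367, adjusted p = 0.0508 with an estimated correlation). Wnt6 was at -2.13 (SE 0.27) and Bmp2 at -2.54 (SE 0.27), detected on 1 of 4 day 10 arrays. Matrix genes fell in 4 of 23 cases, also over the list alone (median -0.44, camera adjusted p = 0.0115, adjusted p = 0.497 with an estimated correlation). Col14a1 was at -2.04 (SE 0.48) and Vcan at -1.32 (SE 0.41). In all, 793 genes changed, 539 up and 254 down (68.0% up, 55.3% with no fold minimum and 86.1% with a 4-fold minimum), and the count was 305 without background correction and 329 with the series matrix values.

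From day 10 (4 arrays) to day 11 (4 arrays) Psg21 rose at least 15.3-fold (adjusted p = 1.57e-17), and Ceacam11, of the same superfamily of adhesion molecules, by 3.63 (SE 0.15, adjusted p = 1.57e-17). The receptor gene Gpr151 was at -2.91 (SE 0.18, adjusted p = 1.21e-13) with detection on 1 of 4 day 11 arrays, and Tac2 at -2.47 (SE 0.36, adjusted p = 7.66e-06). Of 27 trophoblast genes, 12 rose and 2 fell (15 and 3 adjusted over the list alone, median 0.62, or 0.60 with bounds, camera adjusted p = 9.55e-10, adjusted p = 0.00243 with an estimated correlation). Ctsq was at 3.07 (SE 0.15). Yolk sac genes rose in 11 of 14 cases (12 adjusted over the list alone, median 0.86, camera adjusted p = 9.92e-11, adjusted p = 0.00243 with an estimated correlation). Afp was at 2.37 (SE 0.20) and Apoa2 at 1.68 (SE 0.20). Erythroid genes rose in 9 of 13 cases (11 adjusted over the list alone, median 0.88, camera adjusted p = 1.21e-07, adjusted p = 0.0017 with an estimated correlation), and embryonic genes in 7 of 14 (10 adjusted over the list alone, median 0.72, camera adjusted p = 4.84e-06, adjusted p = 0.00335 with an estimated correlation). Hoxc6, a homeobox gene, was at 1.43 (SE 0.25). Of 8 skeletal muscle genes, 3 rose, also over the list alone, with the myosin light chain Mylpf at 1.97 (SE 0.22) and detection on 1 of 4 day 10 arrays (median 0.23, camera adjusted p = 0.035, adjusted p = 0.116 with an estimated correlation). Cell cycle genes rose in 3 of 22 cases and fell in 1, also over the list alone (median 0.54, camera adjusted p = 0.00137, adjusted p = 0.405 with an estimated correlation). Birc5 was at 0.70 (SE 0.20) and Foxm1 at 0.64 (SE 0.16).

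Decidual genes fell in 5 of 22 cases between day 10 and day 11 (7 adjusted over the list alone, median -0.46, camera adjusted p = 0.000178, adjusted p = 0.0105 with an estimated correlation). Prl3c1 was at -2.01 (SE 0.33) and Adamts1 at -1.67 (SE 0.35). Steroid and prostaglandin genes fell in 4 of 12 cases (5 adjusted over the list alone, median -0.65, camera adjusted p = 0.000389, adjusted p = 0.00312 with an estimated correlation). Hsd17b1, an oestradiol-forming enzyme, was at -2.14 (SE 0.23, detected on 2 of 4 day 11 arrays) and Ptges at -1.19 (SE 0.27). Matrix genes fell in 11 of 23 cases, also over the list alone, with Col1a2 at -1.50 (SE 0.35) and a median of -1.03 (camera adjusted p = 5.41e-07, adjusted p = 0.109 with an estimated correlation). Col14a1 was at -2.02 (SE 0.48). Endothelial genes fell in 7 of 19 cases (8 adjusted over the list alone, median -0.67, camera adjusted p = 5.33e-05, adjusted p = 0.233 with an estimated correlation). Pecam1 was at -1.32 (SE 0.27) and Sox17 at -1.04 (SE 0.26). Smooth muscle genes fell in 5 of 15 cases (10 adjusted over the list alone, median -0.59, camera adjusted p = 1.02e-05, adjusted p = 0.277 with an estimated correlation). Myl9 was at -1.01 (SE 0.23) and Mylk at -0.91 (SE 0.18). Macrophage genes fell in 4 of 17 cases (5 adjusted over the list alone, median -0.66, camera adjusted p = 0.00131, adjusted p = 0.396 with an estimated correlation), and interferon genes in 3 of 17 (4 adjusted over the list alone, median -0.60, camera adjusted p = 0.000506, adjusted p = 0.355 with an estimated correlation). Complement genes fell in 1 of 8 cases (5 adjusted over the list alone, median -0.82, or -0.75 with bounds, camera adjusted p = 0.00447, adjusted p = 0.343 with an estimated correlation). In the natural killer list 1 of 12 genes fell (0 adjusted over the list alone, median -0.50, camera adjusted p = 0.0119, adjusted p = 0.293 with an estimated correlation). In the immune regulatory list 1 of 15 fell, also over the list alone (median -0.21, camera adjusted p = 0.048, adjusted p = 0.277 with an estimated correlation), which was Havcr2 at -1.24 (SE 0.19). In all, 531 genes changed, 312 up and 219 down (58.8% up, and 72.4% with a 4-fold minimum), and the count was 123 without background correction and 134 with the series matrix values.

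From day 11 (4 arrays) to day 12 (5 arrays) the placental hormone Prl8a8 rose at least 19.8-fold (adjusted p = 4.3e-25) and the pregnancy-specific glycoproteins Psg21 and Psg18 by 4.09 (SE 0.18, adjusted p = 1.41e-17) and 3.80 (SE 0.16, adjusted p = 7.67e-18). The acute phase genes Orm2 and Orm1 were at -4.25 (SE 0.33, adjusted p = 2.51e-11) and -3.79 (SE 0.42, adjusted p = 8.84e-08), with Orm2 detected on 4 of 5 day 12 arrays. Trophoblast genes rose in 11 of 27 cases and fell in 2 (12 and 3 adjusted over the list alone, median 0.33, camera adjusted p = 2.56e-13, adjusted p = 0.000676 with an estimated correlation). Yolk sac genes rose in 6 of 14 cases (6 rose and 1 fell adjusted over the list alone, median 0.30, camera adjusted p = 0.00194, adjusted p = 0.181 with an estimated correlation). Afp was at 1.02 (SE 0.19) and Fgg at 0.93 (SE 0.15). Erythroid genes rose in 2 of 13 cases (5 adjusted over the list alone, median 0.37, camera adjusted p = 0.00433, adjusted p = 0.0645 with an estimated correlation). Rhag, a red cell membrane protein, was at 0.84 (SE 0.20, detected on 3 of 4 day 11 arrays) and the transcription factor Gfi1b at 0.60 (SE 0.14, detected on 3 of 4 day 11 arrays). Of 8 skeletal muscle genes, 3 rose (3 rose and 1 fell adjusted over the list alone, median 0.06, camera adjusted p = 0.0239, adjusted p = 0.0788 with an estimated correlation). Atp2a1, a calcium pump, was at 1.43 (SE 0.22) and Mylpf at 1.33 (SE 0.21).

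Decidual genes fell in 4 of 22 cases between day 11 and day 12, also over the list alone (median -0.45, camera adjusted p = 0.00194, adjusted p = 0.0477 with an estimated correlation). The serine protease Htra1 was at -2.34 (SE 0.40) and Prl8a2 at -1.07 (SE 0.22). Steroid and prostaglandin genes fell in 5 of 12 cases, also over the list alone (median -0.31, or -0.18 with bounds, camera adjusted p = 0.00167, adjusted p = 0.00604 with an estimated correlation). Cyp11a1 was at -1.07 (SE 0.16). No natural killer gene passed (0 of 12, also over the list alone, median -0.46, or -0.33 with bounds, camera adjusted p = 0.0369, adjusted p = 0.529 with an estimated correlation), the largest difference being Nkg7 at -1.05 (SE 0.57, adjusted p = 0.366). Of 17 interferon genes, 1 fell, also over the list alone, which was Irf1 at -0.54 (SE 0.14, list median -0.36, camera adjusted p = 0.0237, adjusted p = 0.691 with an estimated correlation). In all, 249 genes changed, 135 up and 114 down. The count was 72 without background correction and 84 with the series matrix values, and the share of rises was 54.2%, against 37.5% and 36.9% under those settings.

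The other 13 lists were shifted in no comparison when all arrays were kept, and the counts here are those of day 12 against non-pregnant uterus (5 arrays against 6). The counts over the list alone were the same unless given. Among leukocytes, 3 of 11 T cell genes rose and 6 fell (3 and 7 over the list alone), 1 of 8 regulatory T cell genes rose and 6 fell, 3 of 8 neutrophil genes rose and 5 fell, 1 of 6 mast cell genes rose and 3 fell, 2 of 4 B and plasma cell genes fell, and both eosinophil genes (2 of 2, too few for a list test) fell. Of 16 implantation and progesterone targets, 3 rose and 7 fell, and of 10 uterine gland genes 3 rose and 4 fell, with Spink1, a trypsin inhibitor, at 3.99 (SE 1.16, detected on 2 of 6 non-pregnant arrays). At days 6 and 8, 4 and 5 of the gland genes rose and 4 and 3 fell (medians 0.83 and 1.13, camera adjusted p = 0.449 and 0.273), and non-pregnant replicate 6 was at 1.14 on the list against -1.78 to -1.24. Hypoxia and glycolysis genes rose in 6 of 17 cases and fell in 3, immediate early genes fell in 6 of 13, and polyamine genes rose in 1 of 6 and fell in 4. Mesothelial genes rose in 3 of 7 cases and fell in 2 (3 and 3 over the list alone), and ovary and oviduct genes rose in 2 of 5 and fell in 2.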

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

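Of the tests in this part, those on macrophage and MHC class II genes, on squamous tissue, normalization and oestrous stage for the squamous markers, on low signal and on mislabelling were chosen only after the result was seen, while the other leukocyte and regrouping tests were written before theirs. An array was singled out when its value lay far outside the range of its group by Dixon's test. This singles out about 1 in 20 groups by chance, or 20.3 of 406 groups, and 45 were singled out.

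Macrophage and MHC class II genes were lower at days 11 and 12, with a day 12 median of -2.40 over 30 genes. Dilution of maternal by conceptus tissue predicts an equal fall of the smooth muscle genes. The leukocyte genes fell further by -0.458 (exact permutation p = 0.446) with all arrays and by -0.907 (p = 0.00794) without non-pregnant replicate 4, which was low for the leukocyte lists and high for smooth muscle, so dilution as the whole cause hangs on 1 array and stays open. Normalization between arrays is argued against, since the median was at least as low as -2.39 under median scaling and cyclic loess, a test narrowed after a form with no background correction gave -1.16 and no decision. The dim arrays are argued against as well, with -2.68 without them.

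Of 27 squamous markers 4 rose at day 4 (Krt16, Lor, Krt84 and Sprr1b) and 0 fell, while Krt14 differed by 2.94 with an adjusted p of 0.071. Single arrays of both groups were high and low: Krt14 was 8.22 to 14.34 at day 4 and 5.05 to 12.43 in non-pregnant uterus, Krt13 6.69 to 10.48 and 4.56 to 10.38, and Krt16 4.39 on day 4 replicate 1 against 10.65 to 12.75 on the other 3. Among 18 markers not looked at before, 1 rose and the median was 0.65, above 100% of 10000 random lists, but their mean did not pass when the arrays were permuted (difference 0.67, exact p = 0.319), so tissue of the lower tract in the day 4 samples stays open. Normalization is argued against by the smallest mean of the seen markers under median scaling and cyclic loess, 1.96, and this test was narrowed after its first form gave 1.33 and no decision. Oestrous stage stays open: the oestrogen target list had a median of -0.19, and the labels give no stage.

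The 2 dim arrays were low for macrophage and MHC class II genes. Low signal alone stays open: the percentile was 0 among random lists of matched expression, but their genes need not move together. Fewer leukocytes of all kinds stays open, since 1 of 4 other leukocyte lists was low on both. Exchange of labels is argued against for day 6 replicate 4 (0.0202) and stays open for non-pregnant replicate 4 (-0.0155), tests split by array after the result was seen. Non-pregnant replicate 6 (0.947 with its own group, 0.952 with day 4) and day 4 replicate 1 (0.946, and 0.956 with non-pregnant) were also closer to the other group, so a partner is not ruled out and the 2 groups overlap.

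Non-pregnant replicate 4 had 13097 detected probes against 17410 to 18152 on the other arrays of its group. Its list means, on centred log2 values, were -0.95 for decidual stroma, 1.52 for smooth muscle, -0.19 for macrophages, -0.13 for MHC class II and -0.20 for complement. Cxcl12 was at 8.84, while Prl3c1 at 5.90 and Prl8a2 at 5.80 were not detected and lay below the lowest detected signal of this dim array, 6.03. Day 6 replicate 4 had 13149 detected probes against 16561 to 17491. Its list means were 1.23 for smooth muscle, -1.82 for macrophages, -1.11 for MHC class II, -1.74 for complement, -0.53 for matrix, -1.44 for trophoblast, -0.56 for embryonic tissue, -0.86 for steroid and prostaglandin genes and -0.77 for adipose tissue. Cxcl12 was at 10.20 and Cxcl14 at 12.71, while C1qa at 4.58 and Ido1 at 5.92 were not detected and lay below its lowest detected signal, 6.02.

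Non-pregnant replicate 6 had means of -1.12 for oestrogen targets, 1.14 for uterine glands and -0.95 for mesothelium, and levels of 8.59 for Ltf, 9.25 for Pecam1 and 5.38 for Wnt4. Day 4 replicate 1 had means of -1.14 for oestrogen targets, -0.62 for immune regulatory genes, 0.14 for interferon response, -0.15 for polyamine genes and -0.10 for immediate early genes, with Ltf at 10.59. Oestrogen targets stood at 1.29 on day 6 replicate 5 and B and plasma cells at 0.30 on day 6 replicate 3. Erythroid genes stood at -1.39 on day 8 replicate 2 and adipose genes at 0.69 on day 8 replicate 3. Smooth muscle stood at -0.29 on day 10 replicate 4 and regulatory T cells at -0.14 on day 11 replicate 2. Bmp2 was 5.61 on day 10 replicate 1 and 4.60, not detected, on day 12 replicate 1, Cd3e 7.02 on day 4 replicate 4, and Prl8a2 12.65 on day 12 replicate 5.

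The effects against the shared non-pregnant group differed between successive days by a limma test of the difference itself, for 1129 genes between days 4 and 6, 636 between 6 and 8, 793 between 8 and 10, 531 between 10 and 11 and 249 between 11 and 12. List calls, summed over these 5 comparisons, were 47. Of the detected unnamed probes, 1148 changed at day 12.

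Arrays were regrouped at random up to 100 times (35 for day 10 against day 8 and day 11 against day 10), the real grouping included. At day 4 against non-pregnant 9 of 100 groupings gave at least the real 276 genes, the highest 604, so chance cannot be excluded. Elsewhere only the real grouping (1) reached its count, arguing against chance only if arrays are independent. The highest others were 880 at day 6, 1332 at day 8, 1668 at day 10, 1829 at day 11 and 1666 at day 12 against non-pregnant, then 648, 335, 2, 6 and 142 for the successive days, and 1001 for the F test over 7 groups. For list calls summed over comparisons, at the preset correlation, 11 of 100 groupings reached the real 67 for days against non-pregnant (highest 78) and 43 of 100 the real 47 for successive days (highest 68), so chance cannot be excluded. With an estimated correlation the real 19 and 15 were reached by no other grouping (highest 1 and 1), a test added after the preset result was seen but before its own.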

How the results depend on the processing

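No test in this part was chosen after its result was seen, except that leaving out both dim arrays and averaging near-identical arrays were added after the data were examined. The counts of genes changed moved with the background correction and the fold minimum in every comparison. In the order of days 4, 6, 8, 10, 11 and 12 against non-pregnant, they were 101, 539, 1029, 1159, 1282 and 1298 without background correction and 106, 575, 1088, 1232, 1373 and 1403 with the series matrix values. For the successive days from day 6 against day 4 onwards they were 476, 242, 305, 123 and 72, and 508, 256, 329, 134 and 84. With no fold minimum they were 934, 4043, 5306, 5615, 6060 and 6327, then 2672, 2118, 1879, 1477 and 691. With a 4-fold minimum they were 27, 319, 644, 759, 939 and 961, then 310, 109, 216, 58 and 38.

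Day 4 against non-pregnant, 276 in the report, was 8 with only the 2 groups compared, 649 with array weights, 451 without both dim arrays, 173 with near-identical arrays averaged, and from 185 (without day 4 replicate 2) to 428 (without non-pregnant replicate 4) with 1 array left out. Calls of shifted lists, summed over the 6 comparisons with non-pregnant uterus, were 129 by fry and 19 with an estimated correlation, against 67, and summed over the 5 comparisons of successive days 15 with an estimated correlation, against 47. The share of rises from day 11 to day 12 was 54.2%, and 37.5% without background correction and 36.9% with the series matrix values. It was 53.6% at day 4 (80% under median scaling), 64.0% from day 6 to day 8 (77.3%) and 48.3% from day 4 to day 6 (38.4%).

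The ovary and oviduct list at day 8 against non-pregnant had a median of -0.71, and its called direction was down by camera, which compares with other genes (adjusted p = 0.938), and up by fry, which compares with no change (adjusted p = 7.38e-07). The sign turned in 3 cases, all of 1 gene: Nf1 at day 4, 1.52 with all arrays, was -0.04 without day 4 replicate 2, -0.017 without replicate 3 and -0.083 without replicate 4, and 1.87 without replicate 1. In the 3 cases another probe stood for the gene, and the first probe gave 1.36, 1.43 and 1.41. Same-numbered samples did not move together across groups, so the numbers do not pair samples. With the replicate number as a block, 323 genes changed at day 4, 8472 differed among the groups, and the summed calls of shifted lists were 69 and 49. Every other count stayed within 1.5 times its value, and the genes differing among the 7 groups ranged from 6096 (median scaling) to 11655 (all probes). With 1 array left out, 12124 of 12868 values of named genes kept their sign and their side of the adjusted p threshold. Size was not compared: Prap1 at day 4 counted as kept while going from -3.39 to -1.45 without day 4 replicate 1. The cause was not tested for the other shifts. Signal over background limits what can be said of dim genes: 5912 detected probes have no usable name, and the 2 dim arrays detected 13097 and 13149 probes. No slide block was run.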

Other observations

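Of the tests in this part, the one on the Y-linked gene was chosen only after the result was seen, and the Y-linked and imprinted lists were fixed after the day 12 comparison had been seen. Sct was at 8.48 (SE 0.31) at day 6 and 9.75 (SE 0.32) at day 12 against non-pregnant uterus, while Tac2 was at 7.23 (SE 0.33) at day 8 and was at -2.47 (SE 0.36) from day 10 to day 11. Drd4 was at least 55.01-fold higher at day 6 and was at -4.21 (SE 0.24) from day 8 to day 10. Prss29 was at 7.93 (SE 0.77) at day 6, 7.18 (SE 0.86) at day 8 and 3.24 (SE 0.86) at day 10, and Spink1 at 7.17 (SE 1.10) and 5.94 (SE 1.23) at days 6 and 8. Rrm2 was at 7.18 (SE 0.20) at day 8 and 4.64 (SE 0.18) at day 12, while Birc5 was at 3.35 (SE 0.18) at day 11 and 3.46 (SE 0.17) at day 12.

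If conceptus tissue of either sex is in the samples, Y-linked transcripts could appear with it. Of 4 Y-linked genes 1 was measured, Eif2s3y, detected on 0 arrays through day 8, on 3 of 4 at day 10, 4 of 4 at day 11 and 3 of 5 at day 12. No non-pregnant array detected it, so its difference at day 12 is a bound, at least 1.17-fold. The gene lies near the detection floor, and the day 12 bound of 0.22 log2 decides nothing (the test was first written on the fitted difference, 1.11), so the origin of its signal stays open.

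Imprinted genes are mostly active in placenta and embryo and might rise with them. Of 48 fixed imprinted genes 28 were measured, and 5 of them, seen before or in a fixed list, were left out. Of the other 23, 16 rose, 2 fell and 5 did not pass at day 12, with a median of 1.01, above 100% of random lists matched on expression. Phlda2, a growth-restraining placental gene, was at least 105-fold higher, Peg3 was at 5.57 and Mest at 5.20, while Cd81 fell by -0.85.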
